A study of Mus musculus with 32 samples.

How the data were processed

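The series held 32 mouse samples: 24 bulk RNA libraries, 2 single-cell RNA libraries and 6 CUT&Tag libraries for H3K27ac, the acetylated form of lysine 27 of histone H3 that marks active promoters and enhancers. Groups and replicate numbers were taken from the sample labels. The labels named biological replicates for CUT&Tag, and did not say that bulk RNA replicates came from separate embryos, so p-values measure only the spread between these samples. Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

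Bulk reads were deposited as whole-number counts per gene and library. Per the file headers, the authors made these counts with featureCounts 2.0.1 over exons grouped by gene ID in the GENCODE vM20 annotation, with no strand option and no paired-end option set. Reads of overlapping and antisense gene pairs can therefore be counted for the wrong gene or for none. Per the submitters' processing notes, Trim Galore 0.6.7 and HISAT2 2.2.1 were among the tools and the genome build was mm10 (GRCm38). Bulk RNA was total RNA isolated from cerebral cortices with TRIzol, per the labels' protocols. The count files held 54752 annotated genes, of which 53861 IDs (98.4%) were matched to a symbol. The deposited tables of the whole series, 21531 genes by 18 libraries and 27771 genes by 6 libraries, differed from the files of single libraries in 0 cells.

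Single-cell data were deposited as UMI counts per gene and barcode. Per the submitters' processing notes, Cell Ranger 7.1.0 and Seurat were used, and a deposited metadata table gave the authors' class for part of the barcodes. Peaks were deposited as 1 list per library, with the authors' signal values for each region; these values were not compared between lists. Per the submitters' processing notes, SEACR 1.3.0, Bowtie2 2.2.5 and bedtools 2.30.0 were used, and the names of the deposited lists give the stringent mode of SEACR on the top 0.01 of regions. Because that threshold is set within each library, the number and width of peaks depend on the background of the library.

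Bulk counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter and robust dispersion estimates. The 18 libraries from E13.5 to E15.5 entered 1 fit with 6 stage-by-genotype groups (12 residual degrees of freedom, median prior degrees of freedom 5.96), which tested 21572 genes. Contrasts gave the knockout effect at each stage, its average over the 3 stages, its difference between stages, and E15.5 against E13.5 in controls. The 6 E16.5 libraries had a separate fit with 4 residual degrees of freedom and 18407 genes. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called higher or lower at an adjusted p under 0.05. Fold changes are log2 values with standard errors (SE), and CPM values are counts scaled to library size by TMM and given as mean ± SD over 3 libraries. For a gene with 0 counts in every library of 1 group, the fold is a lower bound against a floor of 3 counts over the group. With few counts, the fold has a 95% exact binomial counting interval. Intervals and floors cover counting error only.

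The 29 fixed gene lists were the targeted genes, class I to IV histone deacetylases (HDACs), HDAC1/2 complex partners, apical progenitor, intermediate progenitor, pan-neuronal, deep-layer neuron, upper-layer neuron, Cajal-Retzius, GABAergic or ventral, cortical hem or choroid plexus, glial, S phase, G2/M phase, CDK inhibitors, p53 targets, Wnt ligands, canonical Wnt targets, Notch pathway, germline, Hox, integrated stress response, immediate early, interferon response, erythroid, microglia, endothelial, pericyte and meningeal fibroblast genes. Some genes were in more than 1 list, such as Cdkn1a, Sesn2, Wnt2b, Wnt3a and Wnt5a. Lists were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation of 0.01, and adjusted over lists within a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move in 1 direction, were run as alternatives. Counts of called members were also adjusted over the list alone.

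Named genes followed a fixed rule. Hdac1, Hdac2 and Wnt9a were named throughout. Each bulk comparison gave its 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM, named symbols and no overlap of libraries between groups. The average and the stage difference gave 5 in each direction, and each list gave up to 4 members with the smallest adjusted p. Single-cell ratios gave 10 in each direction with at least 200 UMI in the higher library and 10 in the lower, and promoters gave 5 in each direction. Genes that stand in the rule or in a list but are left out of the text are not reported here.

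Single-cell UMI counts were summed per library over the cells of the metadata table and divided by the total UMI. With 1 library per genotype no test was made. Ratios carry 95% exact intervals for Poisson counts, shares carry exact binomial intervals, and the position of a list median was given as a percentile among 10000 random lists of the same size matched on mean expression. Genes needed at least 50 UMI over both libraries, and log2 ratios and list medians had 0.5 UMI added to each sum, while the ratios with intervals had not. TMM scaling moved the median log2 ratio of all genes by -0.11 from total-UMI scaling, under which it was 0.11. Doublets were not called again, since the authors' metadata set the cells used. The authors' NPCa and NPCb clusters were merged into 1 progenitor class after their split between libraries was seen. For list medians, a move of up to 0.1 on the log2 scale was counted as no change.

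Peak lists were merged into regions at an overlap of at least 1 bp. Promoters were 2 kb to either side of the annotated start of 21556 genes that also had an RNA test. Genes whose promoter had a peak in at least 2 more lists of 1 genotype were compared with genes with equal numbers of lists by a two-sided permutation test with 100000 resamples. Regions were compared by presence in lists only.

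Depth was 37.5 to 50.5 M counts per library from E13.5 to E15.5 and 35.8 to 43.0 M at E16.5. All pairs of replicates within a group differed by more than sampling noise, so no library was counted as a duplicate. Replicate numbers shared between groups were taken to pair libraries where every same-numbered pair had a correlation of deviations from the group means over 0.1. At E13.5 these correlations were 0.269, 0.131 and 0.108, and at E14.5 0.245, 0.158 and 0.252, so a fit with the replicate number as a block stands beside results of those stages where it changed a call.

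Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper-quartile factors within edgeR, other expression filters, thresholds of 0.01 and of a 2-fold change, fits of the 6 libraries of a stage alone, the replicate block, and leaving out each library in turn. For single-cell data they were all barcodes, TMM scaling, equal class weights and a higher UMI minimum, and for peaks a stricter list, other overlaps and a narrower promoter. Added after the data were seen were embryo sex as a covariate, the omission of E15.5 controls 1 and 2, of genes on the sex chromosomes, of genes on chromosome 17 and of genes of other cell types, and promoter genes matched on expression. Embryo sex was read from Xist, with at least 10000 counts taken as female. Gene sets of other cell types came from E12.5 barcodes outside the metadata table, as genes at least 16-fold higher in marker-positive barcodes with at least 50 UMI. This gave 246 fibroblast and 234 hem or choroid plexus genes. Numbers of set genes called in a comparison and set medians leave out members of the fixed lists, while summed CPM include them.

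The bulk test was tested on simulated data with 200 changed genes. For the E13.5 comparison it recovered 49.3% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 93.9% of those changed 4-fold, and 3 of 150 calls were false. For the Wnt9a comparison the shares were 53.7%, 73.1% and 97%, and 16 of 165 calls were false, a larger share than the 0.05 aimed at. The simulated changes were balanced between rises and falls, and the groups differed in nothing else. In the real data 32.3% of tested genes were called at E13.5, and 88.8% of the Wnt9a calls were upward. The simulated shares therefore need not hold for the real comparisons. Calculations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genome sequence was not used here.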

Results

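To determine how loss of the histone deacetylases HDAC1 and HDAC2 changes the developing mouse cerebral cortex, RNA and H3K27ac were measured in control embryos and in embryos with a conditional knockout of both genes (cKO). Bulk RNA libraries covered embryonic days E13.5, E14.5 and E15.5, with 3 control and 3 cKO libraries at each stage. A separate experiment at E16.5 compared 3 libraries of cortex after in utero electroporation (IUE) of Wnt9a, which encodes a secreted Wnt ligand, with 3 IUE control libraries. The count file header of IUE control 3 names a Wnt9a alignment, against its label, which was followed. Its 16 counts of Col1a1 lay near the 31 and 28 of the other controls, against 3389, 2776 and 2232 with Wnt9a. Col1a1 is a fibroblast gene and not a readout of the construct, so these counts do not decide between header and label. The 271 counts of Ddx3y in IUE control 3 lay below all 5 other libraries, which had 1955 and 1640 in controls and 2567, 2055 and 2411 with Wnt9a. Its 3181 counts of Eif2s3y, another Y-linked gene, lay near the 3540 and 3307 of the other controls, and it had 4 counts of Xist. The cause of the low Ddx3y count was not tested. At E12.5, 1 control and 1 cKO library of cortex were made by droplet single-cell RNA sequencing. H3K27ac was profiled at E13.5 by CUT&Tag in 3 control and 3 cKO libraries of cortex. Total counts per bulk library were 37.8 to 45.1 M in E13.5 controls and 39.1 to 47.4 M in E13.5 cKO. They were 38.1 to 50.3 M and 43.7 to 47.8 M at E14.5, and 37.5 to 46.3 M and 41.2 to 50.5 M at E15.5. At E16.5 they were 35.8 to 40.9 M in controls and 38.5 to 43.0 M with Wnt9a. Mitochondrial genes took 1.24 to 2.09% of counts from E13.5 to E15.5. At E16.5 they took 1.91, 1.82 and 1.81% in controls and 2.75, 1.89 and 2.78% with Wnt9a. Counts of Xist and Y-linked genes gave 1 female and 2 male controls and 3 male cKO libraries at E13.5, and 2 female and 1 male controls against 1 female and 2 male cKO at E14.5. All 3 E15.5 controls were male and all 3 E15.5 cKO were female, so embryo sex and genotype coincided at that stage. All E16.5 libraries were male.

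The targeted genes were examined first. Hdac1 (ENSMUSG00000028800.15, mm10 chromosome 4, 129516104 to 129542713, minus strand) fell in the cKO at every stage, from 126 ± 8.2 to 53.2 ± 3.2 CPM at E13.5, from 146 ± 5.7 to 54.0 ± 2.9 CPM at E14.5, and from 93.5 ± 16 to 43.5 ± 2.6 CPM at E15.5 (SD, n = 3 per group). These were log2 fold changes of -1.24 (SE 0.099, adjusted p = 8.57e-08), -1.44 (SE 0.099, adjusted p = 2.07e-08) and -1.11 (SE 0.099, adjusted p = 9.77e-08). Hdac2 (ENSMUSG00000019777.16, chromosome 10, 36974544 to 37001889, plus strand) fell from 381 ± 7.4 to 108 ± 15 CPM at E13.5, from 219 ± 12 to 88.1 ± 11 CPM at E14.5 and from 391 ± 2.8 to 116 ± 17 CPM at E15.5. The adjusted p-values for Hdac2 were 1.27e-08, 1.64e-07 and 3.06e-09. Both transcripts were lower in each of the 9 cKO libraries than in every control library of the same stage. Counts were summed over whole genes and the deleted exons were not given in the sources used here, so the remaining reads do not measure recombination.

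**Figure D1:**
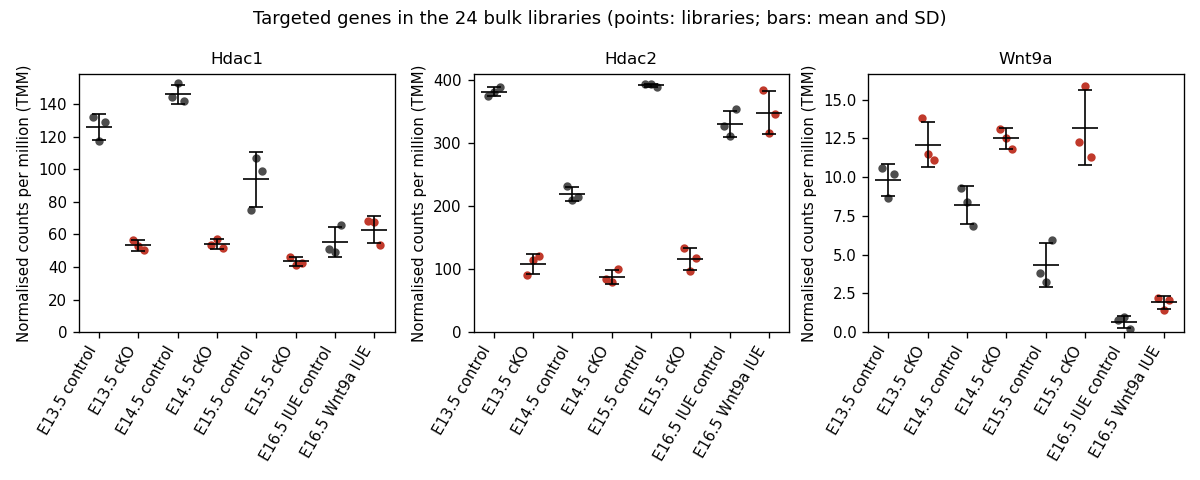
Hdac1, Hdac2 and Wnt9a in each bulk library, in TMM-scaled CPM on the vertical axis, by stage and group on the horizontal axis; points are libraries and bars are the mean and SD of 3. Hdac1 and Hdac2 are lower in all 9 cKO libraries than in the controls of their stage.

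At E13.5, genes of the neurogenic lineage fell and immune genes rose in the cKO, as did some vascular and Wnt target genes; the camera calls for these lists were lost with an estimated correlation. All 11 tested intermediate progenitor genes fell, with a median log2 fold change of -1.27. Among them were the transcription factors of basal progenitors Insm1 (-1.46, SE 0.12, adjusted p = 1.2e-07), Eomes (-1.27, adjusted p = 8e-06), Neurog2 (-1.45) and Neurod4 (-1.94). Neurod6, a transcription factor of postmitotic excitatory neurons, fell from 441 ± 90 to 97.6 ± 2.0 CPM (-2.18, SE 0.152, adjusted p = 6.34e-08), and Neurod2 fell by 1.56 on the log2 scale. H2-Q7, which encodes a nonclassical major histocompatibility class I protein, rose from 1.79 ± 0.38 to 22.4 ± 1.3 CPM (3.63, SE 0.193, adjusted p = 2.06e-09).

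The edgeR test called 3474 genes higher and 3487 lower of 21572 at E13.5. Of these, 1416 rose and 282 fell at least 2-fold. Large rises started from levels near 0 in controls. Vax2, a homeobox gene of ventral eye and forebrain, had 824 counts in the cKO against 2 in controls, a ratio of 410 with a counting interval of 113 to 3390. Atp8b4, a phospholipid-transporting ATPase gene, rose from 0.155 to 9.68 ± 1.6 CPM, and Vdr, the vitamin D receptor gene, rose by 5.60 on the log2 scale. H2-Q6 (4.69), Aspg (4.44), the synaptic link protein gene Hapln4 (4.39), the vesicular zinc transporter gene Slc30a3 (4.26), Plk5 (3.86) and Ankrd34b (3.65) also rose. The largest falls were in the hormone receptor gene Gipr (-2.41) and the secreted protease gene Adamts18 (31.1 ± 5.9 to 5.88 ± 1.6 CPM, -2.40), followed by Neurod6, Sstr3 (-2.09), Rhcg (-2.06), Neurod4, Tiam2 (-1.92), the potassium channel gene Kcna1 (-1.90), the peripherin gene Prph (-1.89) and AI849053 (-1.88).

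Camera placed the intermediate progenitor list below all other genes at E13.5 (adjusted p = 4.96e-13, and adjusted p = 0.087 with an estimated correlation). Of 17 pan-neuronal genes, 6 fell and 2 rose, or 7 fell when adjusted over the list alone (median -0.31, adjusted p = 0.00141, and 0.515 with an estimated correlation); Elavl4 fell by 0.75 and Dcx by 0.64, whereas the neurofilament gene Nefl rose by 1.26. Of 13 deep-layer genes 6 fell and 1 rose (adjusted p = 0.0155, and 0.477 with an estimated correlation), including Tbr1 (-0.67), Bcl11b (-0.62) and Sox5 (-1.23). Of 12 upper-layer genes 5 fell, or 6 adjusted over the list alone (adjusted p = 0.0188, and 0.514 with an estimated correlation). Of 14 G2/M genes 8 fell, or 12 adjusted over the list alone (median -0.45, adjusted p = 0.00222, and 0.573 with an estimated correlation), with Cdk1 at -0.61 and Ube2c at -0.65. Of 15 S-phase genes 4 fell, Pcna among them at -0.72, and 1 rose (adjusted p = 0.0445, and 0.739 with an estimated correlation).

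Of 14 p53 target genes, 9 rose and 1 fell at E13.5 (median 0.40, adjusted p = 0.0121, and 0.186 with an estimated correlation). Sesn2 rose by 1.35, Eda2r by 0.99 and the cell cycle inhibitor gene Cdkn1a by 0.72, while Mdm2 fell by 0.52. Of 7 CDK inhibitor genes 4 rose and 1 fell, without a call for the list (adjusted p = 0.0761); Cdkn2a rose by 3.66 and Cdkn2b by 2.18. Of 13 canonical Wnt target genes 5 rose (median 0.38, adjusted p = 0.0155, and 0.477 with an estimated correlation), among them Tcf7 (0.90), Nkd1 (0.74) and the secreted inhibitor gene Wif1 (1.52). Of 13 Wnt ligand genes 2 rose and 1 fell, namely Wnt7b at -1.0 (list adjusted p = 0.702). Interferon response genes rose in 8 of 10 cases, or in all 10 adjusted over the list alone (median 1.70, adjusted p = 2.94e-05, and 0.273 with an estimated correlation), with Usp18 at 2.21, Bst2 at 1.83 and Oasl2 at 1.80. Markers of other cell types moved with them. Of 11 microglia genes 10 rose (median 1.43, adjusted p = 1.12e-06, and 0.273 with an estimated correlation), including Aif1 (1.58) and Cx3cr1 (1.43). Of 10 endothelial genes 5 rose, or 8 adjusted over the list alone (median 0.72, adjusted p = 0.0155, and 0.573 with an estimated correlation). Of 9 pericyte genes 5 rose (adjusted p = 0.0447, 0.65 with an estimated correlation and 0.0733 with the replicate block). The 11 meningeal fibroblast genes had a median of 0.90 and the list did not pass (adjusted p = 0.317). Of the larger fibroblast set from single-cell data, however, 77 of 213 genes rose and 0 fell, and its sums were 7415, 7380 and 7975 CPM in controls against 11554, 13840 and 13607 CPM in the cKO.

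Deacetylase genes themselves moved both ways at E13.5. The 3 genes named in the design, Hdac1, Hdac2 and Wnt9a, lay below other genes as a list (adjusted p = 2.48e-06, and 0.00638 with an estimated correlation). Of 10 tested HDAC genes 3 rose and 4 fell; the median was 0.07 and the mean -0.28, and camera placed the list below other genes (adjusted p = 0.0358, and 0.186 with an estimated correlation). Both lists hold the deleted genes, so these downward calls restate the knockout. Hdac6 rose by 0.52 and Hdac5 fell by 0.61. Of 18 complex partner genes 7 fell and 2 rose (adjusted p = 0.0445, 0.514 with an estimated correlation and 0.0733 with the replicate block), with the remodeller genes Chd3 at -0.74 and Chd5 at 0.96. Glial genes split, with Apoe at 1.28, Aldoc at -1.80 and Aqp4 at -1.31, so that 3 rose and 2 fell of 12 (adjusted p = 0.836); the list median was positive (0.66) although camera gave the downward direction. Apical progenitor genes rose in 3 and fell in 5 of 20 cases (adjusted p = 0.659), with Hopx at 1.03 and Dbi at -0.86. Cajal-Retzius genes rose in 3 of 9 cases (adjusted p = 0.284), GABAergic or ventral genes in 1 of 15 (adjusted p = 0.362), hem or choroid plexus genes in 1 of 16 (adjusted p = 0.322) and erythroid genes in 1 of 10 (adjusted p = 0.0986). Of 13 Notch pathway genes 5 fell and 1 rose (adjusted p = 0.322), of 9 integrated stress response genes 4 rose and 2 fell (adjusted p = 0.545), and of 8 immediate early genes 2 rose and 2 fell (adjusted p = 0.73). The lists of 6 germline genes (adjusted p = 0.983) and 4 Hox genes (adjusted p = 0.659) did not pass either.

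At E14.5, intermediate progenitor and neuronal markers were lower in the cKO, and most p53 targets and 8 of 13 Wnt target genes were higher; of these list calls only that of p53 targets was kept with an estimated correlation. Of 11 intermediate progenitor genes 9 fell, or 10 adjusted over the list alone (median -1.17), including Insm1 (-1.35) and Eomes (-1.23). Neurod6 fell from 431 ± 77 to 78.0 ± 13 CPM (-2.47, SE 0.153, adjusted p = 2.1e-08) and Neurod2 by 1.68 on the log2 scale. Of 14 p53 target genes 10 rose and 1 fell (median 0.62), with Sesn2 at 1.59, Eda2r at 1.39 and Cdkn1a at 0.93. Wnt9a (ENSMUSG00000000126.11, chromosome 11, 59306928 to 59333552, plus strand) rose from 8.2 ± 1.2 to 12.5 ± 0.62 CPM (0.61, SE 0.189, adjusted p = 0.0197), a call lost without control 3 (adjusted p = 0.102) or without cKO 1 (adjusted p = 0.0621) and at an adjusted p from 0.0029 to 0.0469 under the other libraries left out, tools, scalings, filters and covariate tried. Wnt9a belongs to the hem or choroid plexus set from single-cell data. Of 204 tested genes of that set outside the fixed lists, 68 rose at E14.5 (33.3%, against 16.5% of other genes), with a median of 0.94. At E13.5 the change of Wnt9a had not passed the threshold (9.8 ± 1.0 to 12.1 ± 1.4 CPM, 0.31, adjusted p = 0.232).

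The test called 3633 genes higher and 3345 lower at E14.5. The largest rises included Vax2 (7.06), H2-Q6 (5.68), Atp8b4 (5.62), Vdr (5.49), Hapln4 (4.69), Slc30a3 (4.42), Aspg (4.42), the ephrin receptor gene Epha10 (4.39) and Phldb3 (4.24). The largest falls were Gipr (-2.67), Adamts18 (-2.48), Neurod6, Kcna1 (-2.25), the potassium channel gene Kcnq3 (-2.23), Tiam2 (-2.19), Bmp3 (-2.15), Rgs6 (-2.15), Sstr3 (-2.12) and Neurod4 (-1.98). Camera called 10 lists. The p53 list kept its call with an estimated correlation (adjusted p = 2.19e-04, and 0.0415 with an estimated correlation). The intermediate progenitor list had an adjusted p of 1.19e-09 (0.134 with an estimated correlation). Pan-neuronal genes fell in 8 and rose in 2 of 17 cases (median -0.42, adjusted p = 3.64e-06, and 0.313 with an estimated correlation), and upper-layer genes fell in 8 of 12 (median -0.62, adjusted p = 0.0015, and 0.313 with an estimated correlation). Deep-layer genes fell in 4 and rose in 2 of 13 cases (adjusted p = 0.0583, and 0.0246 with the replicate block). Of 14 G2/M genes 1 passed, downward (adjusted p = 0.032, and 0.679 with an estimated correlation). Wnt target genes rose in 8 of 13 cases (median 0.44, adjusted p = 5.03e-04, and 0.229 with an estimated correlation), with Wif1 at 1.84, Tcf7 at 1.13 and Nkd1 at 0.95. Interferon response genes rose in 7 of 10 cases, or 8 adjusted over the list alone (median 1.39, adjusted p = 0.00159, and 0.36 with an estimated correlation). Beside them, all 11 microglia genes rose (median 1.44, adjusted p = 1.51e-07, and 0.229 with an estimated correlation), and 4 of 16 hem or choroid plexus genes rose (median 0.71, adjusted p = 0.0386, and 0.679 with an estimated correlation), as did 64 of 213 fibroblast set genes. Of 10 endothelial genes 3 rose, or 4 adjusted over the list alone (adjusted p = 0.0684). The targeted genes, with the deleted ones among them, kept their call as a list (adjusted p = 9.93e-05, and 0.0254 with an estimated correlation). As at E13.5, HDAC genes had a positive median (0.10) and a negative mean (-0.24), and glial genes a positive median (0.34) with camera pointing down. The integrated stress response genes had a median of -0.07 and a mean of 0.41.

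Of the 3 stages, E15.5 had the largest number of changed genes, and neuronal genes of deep and upper layers were lower in the cKO. Of 17 pan-neuronal genes 14 fell and 1 rose (median -0.83), of 13 deep-layer genes 10 fell (median -0.89), of 12 upper-layer genes 9 fell (median -0.96) and of 11 intermediate progenitor genes 10 fell (median -1.06). Examples were Neurod4 (-2.97), Neurod6 (-2.55), Insm1 (-1.96), Neurod2 (-1.94), Sox5 (-2.08), Tbr1 (-0.70), Rorb (-1.49) and the neuronal tubulin gene Tubb3 (-1.09). All 13 Wnt target genes rose (median 1.15), among them Wif1 (2.90), Tcf7 (1.98), Nkd1 (1.72) and Axin2 (0.92). Wnt9a itself rose from 4.34 ± 1.4 to 13.2 ± 2.4 CPM (1.60, SE 0.196, adjusted p = 3.19e-06). It is also a member of the hem or choroid plexus set from E12.5 barcodes (212 UMI). Of the tested genes of that set outside the fixed lists, 79.9% rose at E15.5, with a median of 1.72.

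The test called 4981 genes higher and 5333 lower at E15.5, 47.8% of those tested; a fit of the 6 E15.5 libraries alone called 3086 lower. Vdr had 1782 counts in the cKO against 2 in controls, a ratio of 824 with a counting interval of 228 to 6810. Further large rises were Vax2 (7.28), H2-Q6 (6.59), Pirt (5.42), Atp8b4 (4.89), Phldb3 (4.83), H2-Q7 (4.73), Hapln4 (4.70) and the epithelial transcription factor gene Trp63 (4.55). The falls included Gipr (49.4 ± 12 to 3.62 ± 0.8 CPM, -3.77), Rgs6 (-3.63), Itprid1 (-3.20), Sla (-3.18) and Adamts18 (-3.18). Because sex coincided with genotype, Xist and the Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty were also called, with Eif2s3y at least 4670-fold lower in the cKO. These 5 calls were lost without any 1 of the 6 libraries, except that of Eif2s3y without control 3, with adjusted p from 0.0538 to 0.117. Controls 1 and 2 stood apart from control 3 in marker genes of choroid plexus: Ttr, which encodes the choroid plexus protein transthyretin, had 598, 7 and 51693 counts in the 3 controls and 91031, 130395 and 89823 in the cKO.

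By camera, the E15.5 falls had adjusted p-values of 3.45e-08 for pan-neuronal genes (0.158 with an estimated correlation), 1.87e-05 for deep-layer genes (0.147 with an estimated correlation), 5.97e-06 for upper-layer genes (0.147 with an estimated correlation) and 1.48e-06 for intermediate progenitor genes (0.158 with an estimated correlation). Wnt target genes reached 7.4e-09 (0.0668 with an estimated correlation). Of 13 Wnt ligand genes 9 rose and 2 fell (median 1.14, adjusted p = 0.0545), with Wnt2b at 1.01, Wnt5b at 1.29 and Wnt7b at -1.82. Of 14 p53 target genes 8 rose and 3 fell (median 0.76, adjusted p = 3.02e-05, and 0.0668 with an estimated correlation), with Sesn2 at 2.31, Eda2r at 1.83 and Cdkn1a at 1.67. Of 7 CDK inhibitor genes 4 rose and 1 fell (median 0.96, adjusted p = 0.0218, and 0.147 with an estimated correlation). Of 9 Cajal-Retzius genes 7 rose (median 0.59, adjusted p = 0.0121, and 0.158 with an estimated correlation), including Ebf3 (1.45) and Lhx1 (0.77). Of 10 HDAC genes 3 rose and 4 fell (median 0.03, mean -0.37, camera downward, adjusted p = 0.0268, and 0.147 with an estimated correlation), again with the deleted genes among the falls. The 3 targeted genes, of which Wnt9a rose and the other two fell, had an adjusted p of 0.0158 (0.147 with an estimated correlation).

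Markers of other cell types rose together at E15.5. Of 16 hem or choroid plexus genes 11 rose, or 14 adjusted over the list alone (median 1.89, adjusted p = 1.87e-05, and 0.205 with an estimated correlation). Meningeal fibroblast genes rose in 9 of 11 cases, or all 11 adjusted over the list alone (median 2.18, adjusted p = 0.00662, and 0.453 with an estimated correlation), with Col3a1 at 2.41. Endothelial genes rose in 9 of 10 cases (median 1.62, adjusted p = 3.02e-05, and 0.205 with an estimated correlation), with Kdr at 1.74 and Esam at 1.73. Pericyte genes rose in 7 of 9, or 8 adjusted over the list alone (median 0.93, adjusted p = 0.0121, and 0.412 with an estimated correlation). Microglia genes rose in 10 of 11 (median 1.80, adjusted p = 4.05e-06, and 0.175 with an estimated correlation), interferon response genes in 9 of 10 (median 2.08, adjusted p = 1.09e-04, and 0.175 with an estimated correlation) and erythroid genes in 8 of 10, or 9 adjusted over the list alone (median 1.29, adjusted p = 0.00662, and 0.205 with an estimated correlation). The embryonic globin gene Hba-x rose by 2.38 and Slc4a1 by 1.81. The summed CPM of the 246-gene fibroblast set were 5429, 2058 and 8541 in controls and 15551, 20424 and 15824 in the cKO. The G2/M list did not pass (adjusted p = 0.477), and immediate early genes rose in 5 of 8 cases, Egr1 by 2.72 (adjusted p = 0.107). Of 9 integrated stress response genes 4 rose and 4 fell (adjusted p = 0.208), with Trib3 at 2.91.

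**Figure D2:**
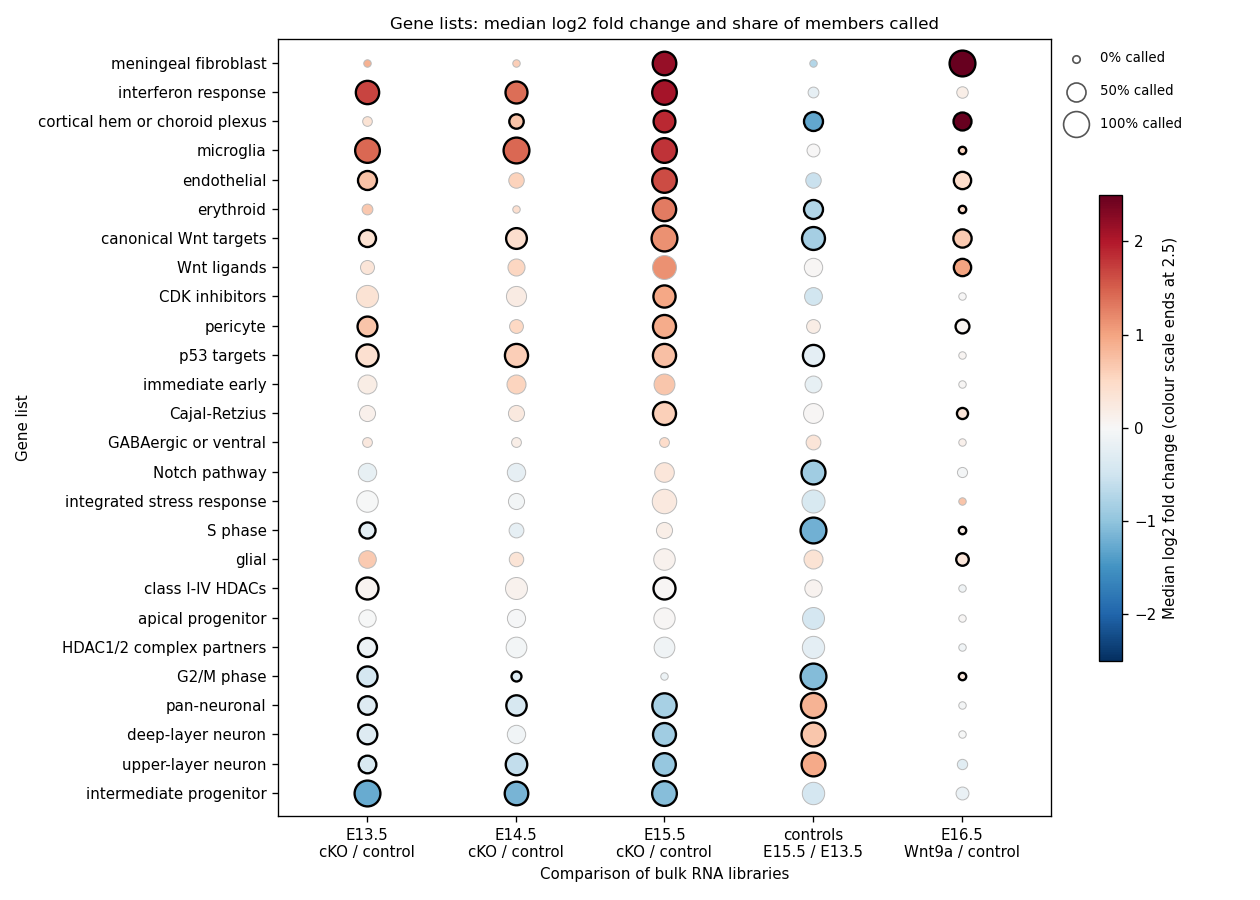
Fixed gene lists on the vertical axis against 5 bulk comparisons on the horizontal axis; circle size is the percentage of tested members called, colour is the median log2 fold change capped at 2.5, and a black outline marks a camera adjusted p under 0.05 at the preset correlation. Intermediate progenitor genes are lower at E13.5, E14.5 and E15.5, with medians of -1.27, -1.17 and -1.06.

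Averaged over the 3 stages, 6313 genes rose and 6263 fell in the cKO. The largest average rises were Vax2 (7.57), Vdr (6.78), H2-Q6 (5.66), Atp8b4 (5.48) and Phldb3 (4.72). The largest average falls were Gipr (-2.95), Adamts18 (-2.69), Rgs6 (-2.50), Neurod6 (-2.40) and the dopamine receptor gene Drd1 (-2.36). All 11 intermediate progenitor genes fell on average (median -1.21, adjusted p = 3.94e-10, and 0.14 with an estimated correlation), 11 of 13 Wnt target genes rose (median 0.72, adjusted p = 1.06e-05, and 0.14 with an estimated correlation), and 10 of 14 p53 targets rose while 3 fell (adjusted p = 1.53e-04, and 0.0619 with an estimated correlation). With the replicate block, the average calls of CDK inhibitors (adjusted p = 0.0371 against 0.0566) and pericyte genes (0.0371 against 0.0527) were lost and that of Cajal-Retzius genes was gained (0.0562 against 0.045). Across stages, 2291 genes were called higher at all 3, and 2143 were called lower, against 134 for independent lists in the latter case. Of genes called at both of a pair of stages, the direction was opposite for 4 of 5167 (E13.5 and E14.5), 36 of 5477 (E13.5 and E15.5) and 42 of 5588 (E14.5 and E15.5). The fold changes correlated across 21572 genes with Pearson's r of 0.688, 0.629 and 0.662 for the same pairs (Spearman 0.71, 0.663 and 0.695); genes are not independent replicates.

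To test whether the knockout effect itself depended on stage, the genotype-by-stage terms were tested together, and 811 genes (3.8%) passed the edgeR threshold. Wnt9a was among them (adjusted p = 0.0264), with log2 fold changes of 0.31, 0.61 and 1.60 at E13.5, E14.5 and E15.5, and a difference of 1.3 between the last and the first (SE 0.27). Its mean level was 12.1, 12.5 and 13.2 CPM in the cKO and 9.81, 8.2 and 4.34 CPM in controls. The larger effect at E15.5 thus lay mostly in lower control values. Hdac1 (adjusted p = 0.316) and Hdac2 (adjusted p = 0.101) did not pass. The effect became more positive from E13.5 to E15.5 for the fatty acid translocase gene Cd36 (by 2.48), Fam183b (2.38), Dmrta1 (2.02), Msx2 (2.01) and Pirt (2.00), and more negative for the activin subunit gene Inhba (-2.40), Hs3st4 (-2.30), the chemokine gene Cxcl14 (-2.12), Usp43 (-2.02) and Ryr3 (-1.93). At an unadjusted p under 0.05 the number was 4246. With embryo sex as a covariate 0 genes passed in edgeR, and 2019 had an unadjusted p under 0.05 in that fit. Without E15.5 controls 1 and 2 there were 427, and DESeq2 called 2070 without the covariate. With the replicate block, Cd36, Fam183b, Dmrta1, Msx2, Pirt, Inhba and Usp43 did not pass (adjusted p from 0.0513 to 0.0817). The Wnt9a call was lost with the sex covariate (adjusted p = 0.365), under which its difference was 1.396 with an SE of 0.356, without E15.5 controls 1 and 2 (0.168), and without E13.5 control 1 or 3, E15.5 control 1, or E15.5 cKO 1, 2 or 3.

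To describe normal maturation over the same period, E15.5 controls were compared with E13.5 controls. Neuronal genes rose and proliferation genes fell. Of 17 pan-neuronal genes 16 rose (median 0.87, adjusted p = 1.17e-12, and 0.14 with an estimated correlation), of 12 upper-layer genes 10 rose, or 11 adjusted over the list alone (median 0.94, adjusted p = 2.83e-06, and 0.14 with an estimated correlation), and of 13 deep-layer genes 10 rose and 1 fell (median 0.69, adjusted p = 4.68e-05, and 0.14 with an estimated correlation). All 15 S-phase genes fell (median -1.20, adjusted p = 1.04e-18, and 0.14 with an estimated correlation), with Cdc6 at -1.45 and Pcna at -1.14, and all 14 G2/M genes fell (median -1.09, adjusted p = 1.68e-14, and 0.14 with an estimated correlation). Wnt target genes fell in 10 of 13 cases (median -0.85, adjusted p = 2.91e-07, and 0.14 with an estimated correlation), Notch pathway genes in 11 of 13 (median -0.89, adjusted p = 6.52e-06, and 0.14 with an estimated correlation) and hem or choroid plexus genes in 8 of 16 (median -1.30, adjusted p = 1.26e-05, and 0.25 with an estimated correlation). In that group E15.5 controls 1 and 2 stood apart from control 3, as sums of the hem or choroid plexus set were 1675, 1038 and 4134 CPM at E15.5 against 3030, 3382 and 3204 CPM at E13.5. Wnt9a fell by 1.18 on the log2 scale (adjusted p = 1.41e-04) and Hdac1 by 0.43 (adjusted p = 0.00194), while Hdac2 had a change of 0.04 (adjusted p = 0.821).

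The age comparison called 3798 genes higher and 4045 lower. The largest rises included Sla (3.67), Jakmip3 (3.56), Pla2g4e (3.48), the AMPA receptor auxiliary subunit gene Cacng3 (3.21) and Inhba (3.12). The largest falls were the embryonic globin genes Hbb-y (823 ± 310 to 15.5 ± 12 CPM, -5.72), Hbb-bh1 (-5.32) and Hba-x (-4.73), followed by Fndc3c1 (-3.63), Hsd3b6 (-3.33), Cdc20b (-2.96) and Hmga2, a chromatin protein gene of early progenitors (-2.94). Of 10 erythroid genes 5 fell (adjusted p = 0.00574, and 0.25 with an estimated correlation). Of 14 p53 targets 7 fell and 2 rose (adjusted p = 0.0429, and 0.173 with an estimated correlation), with Sesn2 at -1.12 and Cdkn1a at -1.0. Apical progenitor genes fell in 11 and rose in 3 of 20 cases (adjusted p = 0.0601), and intermediate progenitor genes fell in 7 and rose in 1 of 11 (adjusted p = 0.0665). The 13 Wnt ligand genes had a median of 0.04 while their mean was -0.25 and camera pointed down (adjusted p = 0.0787). The 4 Hox genes had a fitted median of -0.66, or -0.26 with Hoxb8, at 0 counts in E15.5 controls, placed at its bound. The E14.5 knockout effect, which shares no library with the age comparison, was set against it: 895 genes higher in the cKO fell with age, against 681 for independent lists (Fisher's exact test across genes, one-sided p = 2.04e-22), and 941 genes lower in the cKO rose with age, against 589 (p = 1.59e-61). A further 809 genes were lower in both, against 627 (Fisher's exact p = 8.84e-18), and 656 were higher in both, against 640 (exact p = 0.224); genes are not independent replicates.

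To determine which genes respond to Wnt9a, cortices at E16.5 were compared after IUE of Wnt9a or control. Genes of meningeal fibroblasts and their matrix rose most. All 11 meningeal fibroblast genes rose (median 4.97, camera adjusted p = 2.94e-183, and 0.00275 with an estimated correlation). The fibrillar collagen gene Col1a1 rose from 0.668 ± 0.184 to 67.3 ± 13.1 CPM, Col1a2 by 4.97 (SE 0.121) and Col3a1 by 4.63 on the log2 scale. The retinoic acid synthesis gene Aldh1a2 had 0 counts in the controls and 15.8 ± 4.3 CPM with Wnt9a, at least 603-fold higher. Wnt9a itself was at 0.665 ± 0.39 CPM in controls and 1.93 ± 0.43 CPM with Wnt9a (log2 fold change 1.53, SE 0.447, adjusted p = 0.116), and did not pass the threshold, with adjusted p from 0.00456 to 0.316 over the alternatives. Its counts were 33, 34 and 8 in the controls and 98, 55 and 90 in the Wnt9a libraries; whether transcripts of the construct can be counted was not given in the sources used here. It passed with DESeq2 (0.0269), without an expression filter (0.00456) and without Wnt9a library 2 (0.0435). Wnt9a also belongs to the hem or choroid plexus set from E12.5 barcodes. Of 151 tested genes of that set outside the fixed lists, 27 rose in this comparison (17.9%, against 1.9% of other genes). Hdac1 (0.19, adjusted p = 0.513) and Hdac2 (0.07, adjusted p = 0.726) did not pass.

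The test called 492 genes higher and 62 lower of 18407. Other genes at 0 counts in all 3 controls were the gap junction genes Gjb6 and Gjb2, at least 252-fold and 229-fold higher, and Itih2, at least 204-fold higher. Slc6a13, a GABA transporter gene of the meninges, rose to 19.9 ± 3.1 CPM (8.45, SE 0.359, adjusted p = 1.08e-06), and Cldn11 (7.65), Lyve1 (7.40), Col6a1 (7.38) and Cdh1 (6.82) rose as well. Osr1 had 566 against 2 counts, a ratio of 258 with a counting interval of 71.0 to 2130. The falls were small. Rps2 fell from 519 ± 4.4 to 277 ± 14 CPM (-0.91, SE 0.071, adjusted p = 5.21e-05) and Rps18 from 322 ± 7.4 to 197 ± 24 CPM (-0.71). Both are ribosomal protein genes with processed copies elsewhere, to which their reads may also align. The inflammasome gene Aim2 fell by 1.20. The numbers of calls depended on single libraries, from 316 higher and 15 lower without control 1 to 1221 higher and 1244 lower without Wnt9a library 2. Wnt9a libraries 1 and 3, with the highest mitochondrial shares (2.75 and 2.78%), also differed from the other 4 in the form of the alignment names in their headers, so a batch shared by these libraries is not excluded.

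Of 16 hem or choroid plexus genes 7 rose with Wnt9a, or 15 adjusted over the list alone (median 4.02, adjusted p = 4.28e-19, and 0.116 with an estimated correlation), with Bmp4 at 5.17 and Bmp7 at 2.39. Ttr had 0, 0 and 2 counts in controls and 7352, 504 and 596 with Wnt9a (adjusted p = 0.151). Of 11 canonical Wnt target genes 5 rose, or 7 adjusted over the list alone (median 0.66, adjusted p = 1.3e-06, and 0.116 with an estimated correlation). They were Rnf43 (2.25), Lef1 (1.16), Tnfrsf19 (0.66), Axin2 (0.48) and Ccnd1 (0.33), and without control 1 all but Ccnd1 were lost, with adjusted p of 0.0584, 0.0812, 0.0516 and 0.131. Lef1 was also lost without control 2 (0.0746) or Wnt9a 3 (0.0844), Rnf43 without Wnt9a 3 (0.052), and Axin2 without control 2 (0.0563), control 3 (0.072), Wnt9a 1 (0.0598) or Wnt9a 3 (0.0848). Of 10 Wnt ligand genes 4 rose, or 6 rose and 2 fell adjusted over the list alone (median 1.0, adjusted p = 7.34e-04, and 0.351 with an estimated correlation). Wnt6 was at least 58.6-fold higher, Wnt4 rose by 1.78 and Wnt5a by 1.19. Wnt4 belongs to the fibroblast set from E12.5 barcodes, and Wnt5a is also a member of the hem or choroid plexus list. Whether the ligand genes rose in cortical cells or came with other tissue was not tested. Endothelial genes rose in 4 of 10 cases, or 5 adjusted over the list alone (median 0.46, adjusted p = 2.58e-04, and 0.116 with an estimated correlation), with Cdh5 at 0.95. The lists of Cajal-Retzius (0.0161), glial (0.0295), S-phase (0.0155), G2/M (0.00372), erythroid (0.031), microglia (0.0214) and pericyte genes (0.0206) also passed at the preset correlation, each with an adjusted p of 0.573 with an estimated correlation and at most 2 members past the threshold over all genes. The lists of pan-neuronal (adjusted p = 0.1), deep-layer (0.953), apical progenitor (0.703) and intermediate progenitor genes (0.668) did not pass. Calls for genes higher with Wnt9a overlapped those higher in the cKO in 164 genes at E13.5, against 85.2 for independent lists (Fisher's exact test across genes, p = 2.01e-18), 146 at E14.5, against 88 (p = 6.4e-11), and 404 at E15.5, against 112 (p = 7.25e-178). With the replicate block in both fits, 79 were shared at E13.5 against 67.6 and 81 at E14.5 against 71, so most of the excess at these stages was lost, although replicate numbers did not pair libraries at E16.5. Fibroblast set genes outside the fixed lists were often higher on both sides. They were 124 of 208 with Wnt9a (59.6%, against 1.9% of other genes) and 190 of 213 in the E15.5 cKO (89.2%, against 21.8%). How much of the 404 shared calls such genes make up was not tested. Genes lower both with Wnt9a and in the cKO numbered 17, 10 and 26, against 11.6, 11.1 and 17.6 (Fisher's exact p = 0.0589, 0.692 and 0.0146). The fold changes correlated across 18203 genes with Pearson's r of 0.234, 0.22 and 0.364; genes are not independent replicates.

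**Figure D3:**
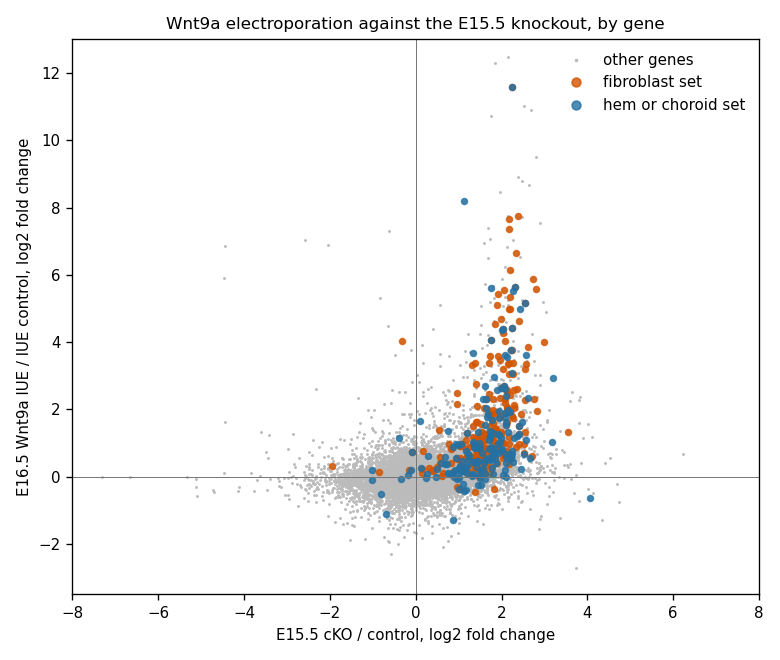
Log2 fold change with Wnt9a at E16.5 on the vertical axis against the log2 fold change in the cKO at E15.5 on the horizontal axis, with 1 point per gene and genes of the fibroblast and hem or choroid plexus sets in colour; genes beyond the axes, such as Xist and the Y-linked genes, are not drawn, and genes at 0 counts in 1 group are drawn at fitted values that are not measured folds. Of the genes called higher with Wnt9a, 404 were also called higher in the E15.5 cKO.

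At E12.5, single-cell data held 15075 barcodes in the control and 16047 in the cKO library, of which 7887 and 7659 were classed by the authors as neural progenitor cells (NPC), intermediate progenitor cells (IPC) or excitatory neurons. With 1 library per genotype, no test was made and intervals cover counting error only. Hdac1 stood at 0.313 of the control level (0.299 to 0.328; 2363 against 8182 UMI) and Hdac2 at 0.287 (0.279 to 0.295; 6000 against 22650 UMI); these are 3' tags and the deleted exons were not given. In NPC the ratios were 0.214 for Hdac1 and 0.193 for Hdac2, against 0.557 and 0.361 in neurons. Over all barcodes that passed a filter on genes and mitochondrial UMI, the log2 ratios were -0.93 for Hdac1 and -1.03 for Hdac2, against -1.68 and -1.80 in the classed cells. Median UMI per cell were 9124 and 8116. NPC made up 50.1% (49.0 to 51.2) of control and 50.5% (49.4 to 51.6) of cKO cells, IPC 17.3% (16.4 to 18.1) and 18.8% (17.9 to 19.7), and excitatory neurons 32.6% (31.6 to 33.7) and 30.7% (29.7 to 31.7). The NPC class combined the clusters NPCa, with 29 control and 3854 cKO cells, and NPCb, with 3921 control and 15 cKO cells.

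The largest ratios of cKO to control at E12.5 were those of Tcea3 (30.1, 16.6 to 61.0), Gchfr (642 against 41 UMI, ratio interval 12.4 to 23.9), the small heat shock protein gene Hspb1 (13.5, 8.14 to 24.2), Galnt12 (12.6), Fam131c (12.4), the class II histocompatibility gene H2-Ab1 (10.4), Chchd10 (10.0), Tagln2 (9.95), Col26a1 (9.75) and Tubb6 (9.66). Of these, Tcea3, Hspb1 and Galnt12 belong to the hem or choroid plexus set and Col26a1 and Tubb6 to the fibroblast set. In classed cells, however, the fibroblast list summed to 5.77 CPM in the cKO and 6.39 CPM in the control, and its abundant member Col3a1 had 53 against 89 UMI. No excess of fibroblast list transcripts thus stood beside the rises of Col26a1 and Tubb6. For Tcea3, Hspb1 and Galnt12 the values were mixed. Ttr was lower in the cKO, but the hem or choroid plexus list summed to 141 CPM in the cKO and 111 CPM in the control. Whether other cells among the classed ones brought these rises was not tested. With 0.5 UMI added to each sum, over all barcodes that passed the filter, the log2 ratio of Tcea3 was 1.19 rather than 4.85, that of Hspb1 0.65 rather than 3.72 and that of Col26a1 0.51 rather than 3.27. The lowest were those of Shox2 (0.0389, 0.0205 to 0.0674), the transcription factor gene Nr2f2 (0.155, 0.148 to 0.162), Mctp1 (0.182) and Cck (0.207), followed by the targeted genes and the histone genes Hist1h4k (0.335) and Hist1h4h (0.351). The p53 target list had a median log2 ratio of 0.46, at percentile 99.8 among matched random lists, with Cdkn1a at 3.38-fold (3.0 to 3.81; a log2 ratio of 0.37 rather than 1.75 over all barcodes) and Sesn2 at 2.7-fold (2.28 to 3.22). Wnt target genes had a median of 0.25 (percentile 94.1), with Wif1 at 2.2-fold and Tcf7 at 2.19-fold. Apical progenitor genes were at 0.20 (percentile 99.6), and Hopx stood at 2.7-fold. Hem or choroid plexus genes were at -0.36 (percentile 0.0), with Ttr at 0.51 (0.459 to 0.566), but Bmp7 at 2.59-fold. The intermediate progenitor list had a median of 0.0 (percentile 29.6) and the pan-neuronal list -0.01 (percentile 41.4). Wnt9a had 29 UMI in the cKO and 26 in the control (ratio 1.21, 0.687 to 2.14), so a difference was not detectable at this depth.

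Single-cell ratios were compared with bulk fold changes across genes. Over 13608 genes, the E12.5 ratios correlated with the E13.5 fold changes with Pearson's r of 0.593 (Spearman 0.606), with E14.5 at 0.583 (Spearman 0.597) and with E15.5 at 0.324 (Spearman 0.498); genes are not independent replicates. Of 2579 genes called higher at E13.5, 93.4% were higher in the E12.5 cKO cells, against 64.1% of all genes compared, and of 3112 called lower, 67.3% were lower, against 35.9%.

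**Figure D4:**
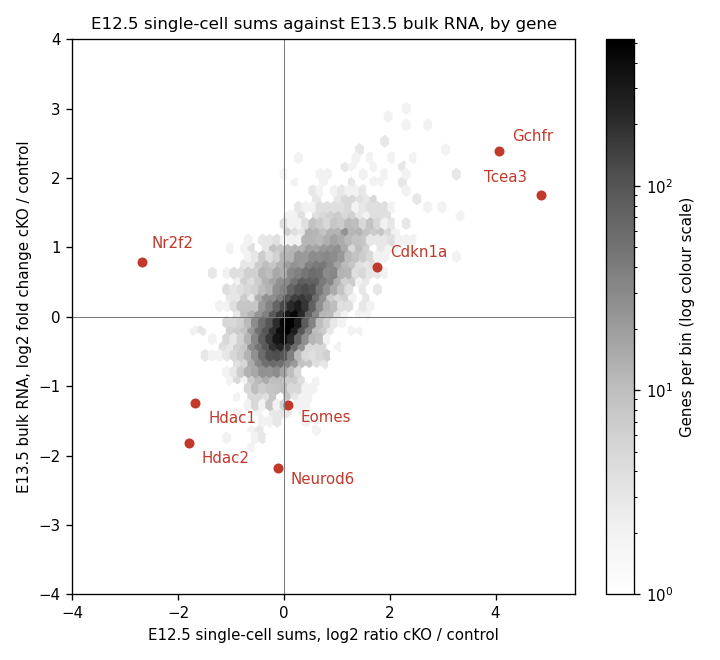
Log2 ratio of summed UMI in the E12.5 cKO over the control library on the horizontal axis against the E13.5 bulk log2 fold change on the vertical axis; grey shading counts genes per bin on a log scale, red points are single named genes, and genes beyond the axes are not drawn. Pearson's r over 13608 genes was 0.593.

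To determine how H3K27ac differed between genotypes, E13.5 peak lists were compared with each other and with RNA. Promoters that carried a peak in at least 2 more cKO than control lists belonged to 1736 genes, whose median E13.5 RNA log2 fold change lay 0.41 above that of genes with equal numbers (permutation p = 1e-05, the smallest possible). Without control list 1, 2 or 3 there were 584, 709 or 819 such genes, and without cKO list 1, 2 or 3 there were 1820, 1288 or 1285. Every cKO list had peaks at more promoters (55.3 to 64.1%) than any control list (47.7 to 54.8%). The numbers of genes with more or fewer cKO lists therefore do not measure a net gain of H3K27ac. For the 1736 genes the difference was 0.34 when genes with equal numbers were matched on control CPM. These tests run across genes, which are not independent replicates. Of the 1736 genes, 32.5% were called higher in RNA, against 14.2% of 9340 genes with equal numbers (Fisher's exact test, p = 8.5e-68), and 9.9% were called lower, against 24.3%. Vax2 (chromosome 6, transcription start 83711264, plus strand) had a promoter peak in all 3 cKO lists and no control list, as did Zbtb46 (chromosome 2, 181459426, minus strand; RNA 1.80), Tnfaip2 (chromosome 12, 111442469, plus strand; 3.20), H2-Q4 (chromosome 17, 35379617, plus strand; 2.15) and Cgn (chromosome 3, 94786492, minus strand; 1.36). The reverse held for Fdft1, an enzyme gene of sterol synthesis (chromosome 14, 63179578, minus strand; RNA -1.16), Nxph4 (chromosome 10, 127534559, minus strand; -1.14), Hpca (chromosome 4, 129122036, minus strand; -0.91), Gjc1 (chromosome 11, 102819700, minus strand; -0.54) and Ttbk1 (chromosome 17, 46487675, minus strand; -0.50). For the 327 genes with fewer cKO lists no difference of medians was detected (0.01, permutation p = 0.854), while both fewer were called higher (8.9%, Fisher's exact p = 0.00566) and fewer were called lower (15.3%, Fisher's exact p = 0.000123) than among genes with equal numbers. The difference of medians was 0.06 without control list 2 (permutation p = 0.0167) and -0.04 without control list 1 (permutation p = 0.0499), and without cKO list 1, 2 or 3 there were 92, 78 or 136 such genes. The 48 of the 327 genes with peaks in 3 control lists and no cKO list had a difference of -0.13 (permutation p = 0.0458). Promoter peaks at Hdac1, Hdac2 and Eomes were present in all 6 lists, and at Neurod6 in 2 control lists and no cKO list. Wnt9a had one in 3 cKO and 2 control lists. Of the largest RNA rises, H2-Q6 had a promoter peak in all 6 lists, H2-Q7 in 3 cKO and 2 control lists, Hapln4 in 2 and 1, Vdr in 1 and 0, and Atp8b4 and Slc30a3 in no list.

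Lists held 16692, 18712 and 20271 peaks in controls and 19132, 21817 and 21563 in the cKO (18560 ± 1790 against 20840 ± 1480, exact permutation p = 0.2, two-sided, smallest possible 0.1). They covered 171.1 ± 28.2 Mb in controls and 139.8 ± 21.2 Mb in the cKO, with median widths of 6982 ± 1720 and 5346 ± 1030 bp. Merging gave 26086 regions, of which 9229 were in all 6 lists, 712 in all cKO and no control lists, and 293 in all control and no cKO lists. Jaccard indices were 0.621 to 0.705 within a genotype and 0.545 to 0.651 between genotypes. The share of promoters with a peak was 47.7, 54.6 and 54.8% in controls and 55.3, 60.3 and 64.1% in the cKO. Since the lists differed in these ways, the 712 and 293 regions do not measure a net gain of H3K27ac.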

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

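The tests of other tissue and of other splits of the libraries in this part were chosen after the results were seen, as were the fits without E15.5 controls 1 and 2 and with embryo sex; the test of the sex coefficient was set down before its result was seen, and the test between stages before the data were examined.

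The knockout effect differed between stages for 811 genes in a test of the difference itself. The following values are the E15.5 minus the E13.5 effect on the log2 scale. Among Wnt pathway genes, the difference was 1.3 for Wnt9a, 0.70 for Wnt2b, 0.76 for Wnt5b, 1.13 for Rspo1, 1.08 for Tcf7, 1.03 for Sp5, 0.98 for Nkd1 and 0.75 for Axin2, but -0.82 for Wnt7b. Wnt9a, Rspo1, Fam183b and Msx2 belong to the hem or choroid plexus set. Genes of that set outside the fixed lists had a median effect of 0.57 at E13.5 and 1.72 at E15.5. Among genes of the cell cycle and p53 response the difference was 0.95 for Cdkn1a, 0.96 for Sesn2, 0.89 for Phlda3 and 0.91 for Ccne1. Among neuronal and layer genes it was -0.45 for Pou3f3, 0.68 for Ebf3 and 1.82 for Prph, and among other list members 1.02 for Esam and -1.14 for Ptprz1. It was 1.10 for H2-Q7, 1.02 for Bmp3, 2.00 for Pirt, 2.48 for Cd36, 2.38 for Fam183b, 2.02 for Dmrta1 and 2.01 for Msx2. It was -2.40 for Inhba, -2.30 for Hs3st4, -2.12 for Cxcl14, -2.02 for Usp43 and -1.93 for Ryr3. With the replicate block, Cd36, Fam183b, Dmrta1, Msx2, Pirt, Inhba and Usp43 did not pass (adjusted p from 0.0513 to 0.0817). The number of genes ranged from 122 without E15.5 cKO 2 to 2238 without E15.5 control 3. It was 4 of 100 drawn splits, the real one included, that gave as many genes, but this share does not say whether chance can be excluded, because exchanging genotypes within stages puts the knockout effect itself into the residual spread. The highest other split gave 5057 genes, several times the real number. That draw exchanged the genotypes at 2 stages and not at the third, so the knockout effect itself enters its difference between stages.

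Embryo sex, acting alike at each stage, would need a sex coefficient of similar size in the E13.5 and E14.5 libraries, which hold both sexes. Its median size over the autosomal genes was 0.101 of the median difference of the effects (0.07 against 0.65, and 0.06 in uncalled genes matched on expression), which argues against such an effect as the cause. Against this reading, the female minus male coefficient and the difference of the effects had a correlation of 0.346 across those 784 genes, which are not independent replicates and whose E13.5 libraries enter both values. With sex as a covariate the number of genes in edgeR fell to 0, the median SE went from 0.152 to 0.197 and the median size of the difference from 0.65 to 0.58, and which of these ended the calls was not tested; for Wnt9a the difference went from 1.3 (SE 0.27) to 1.396 (SE 0.356); 2019 genes had an unadjusted p under 0.05 in that fit. Other tissue in the dissected samples stays open. With the fibroblast and hem or choroid plexus sets left out 792 genes were called, but the sets held only 434 tested genes, too few for their omission to decide. A sex effect at E15.5 alone cannot be told apart from genotype there, as all controls were male and all cKO female, and a true dependence on stage stays open and untested.

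Barcodes outside the authors' classes were not used in the comparisons. Of 7064 such cKO barcodes that passed a filter, 12.1% carried markers of GABAergic or ventral cells, above the 10.0% (9.27 to 10.9) of 5638 control barcodes, and 6.74% (6.16 to 7.35) carried erythroid markers, above 3.44% in the control. Over all barcodes that passed the filter, however, the erythroid list summed to 12170 CPM in the cKO and 12150 CPM in the control library. With 1 library per genotype the shares of barcodes have no replicate check.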

How the results depend on the processing

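The alternatives that used embryo sex, that left out E15.5 controls 1 and 2, or genes of the sex chromosomes, of chromosome 17 or of other cell types, and the matched promoter genes, were chosen after the data were seen; the others were set before. Of 385 alternative values for main results, 285 stayed on the same side with the same direction or within the tolerance, and of 5774 for named genes and lists 5302 did. Most named genes were picked in these data for a large change or a small adjusted p. The latter share is therefore partly set by that choice and does not describe genes in general. Unless a cause is named, the cause was not tested.

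Besides the calls printed in the report, the replicate block changed no other call of a named gene or list at E13.5, at E14.5 or on average; over all genes it gave 6770 calls at E13.5, 6765 at E14.5, 12390 on average and 892 for the stage difference, of which 6392, 6387, 12066 and 576 were also called without it. E15.5 pairs had correlations of -0.049, -0.238 and -0.111 and E16.5 pairs 0.116, -0.012 and -0.295, and no control there correlated best with its own number, so the samples were taken to share only a number. The block gave 10117 and 490 genes there, and 7550 between ages. The Wnt9a lists of upper-layer and integrated stress response genes passed with it (adjusted p = 0.0119 and 0.0139), and the p53 list between ages did not (0.0573). Of the named genes, Cd36, Fam183b, Dmrta1, Msx2, Pirt, Inhba and Usp43 did not pass for the stage difference under the block (adjusted p from 0.0513 to 0.0817), nor did the Y-linked genes at E15.5 (0.141 to 0.148), Rec8 between ages (0.168), or Spint2, BC051226, Neurod4, Hey2 and Apoe with Wnt9a (0.0632 to 0.0993). With the block, lists past the threshold were 13, 11, 17, 15, 9 and 14 at E13.5, E14.5, E15.5, average, ages and Wnt9a. Calls shared with the cKO under the block were 79 and 81 higher at E13.5 and E14.5 (67.6 and 71 for independent lists), and 17 lower at E14.5 (13.7).

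Stricter thresholds leave fewer genes by construction. At an adjusted p under 0.01, 2287 and 2211 genes remained higher and lower at E13.5, 2383 and 2127 at E14.5, 73 for the stage difference and 278 and 12 with Wnt9a. With a 2-fold change the numbers were 1416 and 282, 1486 and 355, 3013 and 901 at the 3 stages, 2576 and 469 on average, 1297 and 759 between ages, 201 for the stage difference and 7 lower with Wnt9a. The 6 libraries of E15.5 alone called 3086 lower. DESeq2 gave 2070 for the stage difference and 834 and 300 with Wnt9a. Without a filter Wnt9a gave 880 and 387, at 2 CPM 30 lower, without fibroblast or choroid plexus genes 289 and 37, and without chromosome 17 37 lower. The stage difference was 0 with embryo sex (2019 at an unadjusted p under 0.05) and 427 without E15.5 controls 1 and 2. At an unadjusted Wnt9a p under 0.05, shared calls were 621 higher and 437 lower at E13.5, 595 and 412 at E14.5, and 1124 and 755 at E15.5.

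With an estimated correlation, the lists past the threshold were 1 at E13.5, 2 at E14.5, 0 at E15.5, 1 on average, 0 between ages and 1 with Wnt9a, against 15, 10, 17, 16, 10 and 12; fry gave 17 at E14.5, 20 between ages and 5 with Wnt9a.

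Leaving out 1 library gave from 122 (without E15.5 cKO 2) to 2238 genes (without E15.5 control 3) for the stage difference, with over 1.5 times of change in 14 of 18 cases, and from 316 higher and 15 lower (without control 1) to 1221 and 1244 (without Wnt9a 2) at E16.5, with such a change in 2 of 6 cases for higher and 6 of 6 for lower genes. The cKO-only regions ranged from 877 to 1344 and the control-only regions from 439 to 608, under a rule with fewer lists; the promoter difference ranged from 0.37 to 0.55 for more and from -0.059 to 0.059 for fewer cKO lists, and the cKO minus control differences per list from 1346 to 3135 peaks, from -42.4 to -15.5 Mb covered and from -2334 to -673 bp in width. Cases that reversed for fewer cKO lists were -0.043 without control 1, -0.059 without cKO 2 and -0.042 without cKO 3; further reversals were -0.021 with the stronger part of each list by maximum signal, -0.127 for 3 lists against 0 and -0.083 against matched genes. The cKO-only regions were 424 with that stronger part of each list, and control-only regions 491 where a peak had to cover most of a region.

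In single cells, all barcodes gave shares of 9.77 and 10.1% IPC, 26.3 and 29.2% NPC and 15.9 and 19% neurons (cKO and control), since unclassed barcodes enter the total. The log2 ratio of Hdac1 was -1.79 with TMM, -0.93 over all barcodes and -1.39 with equal class weights, and that of Hdac2 -1.91, -1.03 and -1.55. The correlation with E15.5 bulk was 0.324. Reversed were Eomes (-0.042 with TMM, -0.04 over all barcodes), Neurod6 (0.019 with equal class weights) and the erythroid median (-0.043 over all barcodes). In bulk, the stage difference of Hdac2 reversed to -0.051 without E13.5 cKO 1 and -0.049 without E15.5 cKO 1 (highest 0.17, without E15.5 cKO 2), and with the sex covariate E15.5 Xist (-0.70, adjusted p = 0.137) and Uty (0.11, adjusted p = 1) reversed. Depth limited Wnt9a in single cells, with 29 and 26 UMI. Genes that a filter or an omitted set removed have no value under that setting.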

Other observations

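The tests of fibroblast and choroid plexus genes, of chromosome 17 and of the splits below were chosen only after the results were seen; the test of the Dynlt1 copies was set down before its result was seen.

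Single-cell ratios differed by class at E12.5. In excitatory neurons all 11 intermediate progenitor genes were higher in the cKO library (median log2 ratio 0.36, percentile 100 among matched lists), whereas in IPC 10 of the 11 were lower (median -0.25, percentile 1.5). Apical progenitor genes had medians of 0.42 in neurons (percentile 100), 0.27 in IPC (99.9) and 0.13 in NPC (95.8), where the NPC value compares cluster NPCa of the cKO with NPCb of the control. In IPC all 15 G2/M genes were lower (median -0.22, percentile 0.8). In NPC, deep-layer genes had a median of 0.60 (percentile 100), p53 targets 0.68 (percentile 100) and Cajal-Retzius genes 1.04 (percentile 99.0). Globin and other erythroid genes were higher in every class, with medians of 1.28, 0.94 and 0.89 in NPC, IPC and neurons, but over all barcodes that passed the filter the erythroid median was -0.04.

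Among barcodes outside the classes, markers of vascular and covering tissues were rarer in the cKO library. Hem or choroid plexus markers were on 6.01% of control and 3.04% of cKO barcodes, fibroblast markers on 3.28% and 0.849%, endothelial markers on 1.21% and 0.311%, and pericyte markers on 0.834% and 0.411%. Cajal-Retzius markers were on 4.74% and 5.14% and microglia markers on 0.709% and 0.609%. Over all classed cells, list medians at E12.5 were 0.25 for upper-layer genes (percentile 95.2), 0.33 for CDK inhibitors (97.7), 0.50 for immediate early genes (95.3) and 0.44 for Cajal-Retzius genes (97.9).

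Rises of fibroblast and choroid plexus genes with Wnt9a were followed up. Members of the fixed lists were left out of this test. Of the other fibroblast set genes, the 50 with the most UMI were taken, and 74% of them (37) were called higher. All 50 had positive fold changes (median 1.27), so cells of another tissue in the dissected samples may account for these rises. Of the genes called higher, 67.9%, 334 of 492, lay outside both sets, including Axin2, Lef1, Ccnd1, Rnf43 and Tnfrsf19. Aldh1a2 and Slc6a13 of the meningeal fibroblast list also lay outside both sets, so this share cannot argue against other tissue. A response of electroporated cortical cells to Wnt9a stays open. The fibroblast set summed to 2603, 2598 and 2441 CPM in the controls and 5484, 4759 and 5075 CPM with Wnt9a. These explanations cannot be told apart here, because tissue of the samples was not sorted and the sets hold only genes strongly enriched at E12.5.

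Falling genes in the Wnt9a libraries clustered on chromosome 17, which held 20 of the 62 among 876 tested genes (Fisher's exact test, adjusted p = 7.92e-11). The densest 20 Mb, from 6256860 to 25233331, held 13 of the 20, against a median of 10 in random draws (permutation p = 0.123), so a strain variant on chromosome 17 stays open. The summed counts of the 4 near-identical Dynlt1 copies fell by 0.43 on the log2 scale (SE 0.07, adjusted p = 0.00817). That argues against a mere exchange of reads between copies. Dynlt1a had 548, 465 and 356 counts in controls and 348, 307 and 303 with Wnt9a. Dynlt1c, however, had 332, 324 and 249 in controls and 384, 357 and 323 with Wnt9a. Reads assigned to no copy do not enter the sum, so shared reads are not excluded. Tests for other causes were not made.

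Other splits of the libraries were counted for each comparison. Only 1 of the 10 splits, the real one, gave as many genes at E13.5 (6961, highest other 2), at E14.5 (6978, highest other 5), at E15.5 (10314, highest other 2), between ages (7843, highest other 0) and with Wnt9a (554, highest other 13), and 10 splits are too few for a share under 0.05. The same holds for H3K27ac regions in all lists of 1 genotype and none of the other (1005, highest other 273). For the average over stages 1 of 100 drawn splits gave as many genes, which argues against chance; the real number was 12576 and the highest other 9396, from a draw that kept the real genotypes at 2 stages.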
